A study of Homo sapiens with 33 samples.

How the data were processed

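Total RNA of established cell lines, astrocytomas and breast tumours had been hybridized to 2 types of Affymetrix arrays, the breast tumours to the smaller type and all other samples to the larger. Uptake in the lines had been measured in 3 wells per line after 2 h with FDG in medium with 10% serum, per the labels, and the labels give only high or low. The deposited values were intensity values (linear probe set signal), normalized by the authors. GCOS 1.3 is named in the submitters' processing notes, and the summary method, background correction and scaling target were not given in the sources used here. From the values, the cell line arrays were scaled to 1 trimmed mean (2499.57 to 2499.64 between percentiles 2 and 98), and the astrocytoma and the breast arrays had nearly equal quantiles on scales of their own. The deposited values of 10 cell line arrays were written with 1 decimal and those of 8 with more, so they were exported in at least 2 ways. Each of the 3 kinds of samples was therefore analysed apart.

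Values were put on the scale log2(value + 16). The annotation gave 1 gene for 41097 of 54675 probe sets of the larger array and for 19071 of 22283 of the smaller, and symbols were updated through Entrez identifiers. Probe sets of several genes were left out, which left no probe set for SLC16A3, G6PD and CA9, and so were 66 and 34 probe sets of sex-linked genes that were not to be examined. Each gene was represented by its probe set with the highest mean. A gene was tested when its value lay above its array's median in as many samples as the smaller group holds. Genomic positions were not given, since no comparison rests on them.

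The 2 arrays of a cell line were averaged, so that n = 3 lines against 3, and nothing in the labels says whether they came from separate cultures. Array numbers did not pair the lines: deviations of arrays with the same number correlated with r = -0.03 to 0.23 over 15 pairs. The arrays of an astrocytoma label differed by a robust SD of 0.0844 to 0.0862, against 0.357 to 0.732 between breast tumours and 0.130 to 0.400 between arrays of a cell line, so each astrocytoma label was counted as 1 sample. Arrays of different astrocytoma labels differed by 0.293 to 0.302, also less than any 2 breast tumours, which were on another array type. These values therefore do not show whether the 2 labels came from different tumours. The planned limma test of 2 against 2 had been run and gave 2078 higher and 3289 lower genes with an adjusted p under 0.05. Its spread is that between arrays of what may be 1 sample, so it was set aside and nothing in the report rests on it. Astrocytoma genes were counted when they differed at least 2-fold in every pairing of arrays, and a list's median was set against 10000 random lists drawn from the same of 20 expression bins, with bounds at percentiles 2.5 and 97.5. Nothing in the labels says that each breast tumour came from another person.

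Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists of genes were tested with camera at its preset inter-gene correlation of 0.01, again with correlation estimated, and with two-sided exact permutation tests of list scores, which are means of gene-centred log2 values. The 36 lists cover metabolism, growth, stress, immune and other cell types and tumour lineages, and a list needed 5 tested members. They were written from textbook knowledge, and the named genes fixed by rule, before the data were examined; MYC and basal-like lists are not blind to the series title. Genes named were a fixed set around glucose use, MYC and breast subtypes, the 6 highest and 6 lowest by moderated statistic among genes whose groups did not overlap, and the 3 leading members of each called list. In the astrocytomas the rule used the fold in place of the statistic, again among genes whose groups did not overlap. The signature took 100 genes per direction from the cell lines. Correlations across tumours had permutation tests with 100000 resamples. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

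The design was tested on simulated data with the spread of these samples. Simulated genes were drawn independently of each other, so the list counts below do not show how often camera calls lists of correlated genes. For 3 lines against 3, genes shifted by log2 1, 2 and 3 were recovered in 0%, 0.448% and 6.67% of cases, and a glycolysis list shifted by 0.5 was called in 18 of 20 simulations, with 2 calls among 660 lists of simulations without a shift. For 5 tumours against 6, the shares recovered were 68.1%, 92.8% and 97.7%, the shifted list was called in 20 of 20, and 0 of 680 lists without a shift were called. Of all genes called, 6.93% and 5.59% had not been shifted. Alternatives covered normalization between arrays, pseudocounts of 1 and 64, the filter, the choice of probe set, the prior of eBayes, the correlation of camera, the handling of the 2 arrays per line, the size of the signature and leaving out each sample. A pseudocount of 0 in the tumours, a larger one in the cell lines and the use of the export style were added after the data had been seen.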

Results

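RNA levels were measured on 33 Affymetrix arrays in 3 kinds of human samples that the labels sort by uptake of fluorodeoxyglucose (FDG), a glucose analogue that cells trap after the first step of glycolysis. The cell lines comprised 3 with high uptake (LNCAP, a prostate cancer line; SKmel28, a melanoma line; U87, a glioma line) and 3 with low uptake (CHL, a melanoma line; LAPC4, a prostate cancer line; SF268, a glioma line), with 2 arrays each. A further 6 breast cancer lines, called a prediction set by the labels, carried no uptake label and had 1 array each. The tumours comprised 5 breast tumours with high and 6 with low uptake, 1 array each, and 4 astrocytoma arrays, 2 per uptake label. The median signal was 329 to 446 on the 18 cell line arrays, 4.97 to 5.06 on the astrocytoma arrays and 127 to 131 on the breast arrays. All differences below are FDG-high minus FDG-low on the log2 scale, and the number of samples limits their precision.

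The cell line comparison asked which transcripts go with FDG retention in culture. Targets of p53, a stress-response transcription factor, rose in the FDG-high lines by a mean log2 fold of 0.97 over 15 measured genes (n = 3 lines against 3, adjusted p = 2.2e-05, but adjusted p = 0.200 with an estimated correlation). Among them, SCO2 differed by 1.16 (SE 0.35), ZMAT3 by 1.296 (SE 0.41) and the death receptor gene FAS by 2.03 (SE 0.80). Genes of glycolysis rose by a mean of 0.44, with 16 of 19 measured members higher (adjusted p = 0.0355), but adjusted p = 0.617 with an estimated correlation. The call held in 1 of the 6 fits that each left out 1 line. Such a fit leaves another line without its partner of the same origin, so a lost call can reflect origin as well as uptake. The glycolysis score was higher in the FDG-high line of each origin. It was 0.18 in SKmel28 and -0.37 in CHL, -0.004 in LNCAP and -0.42 in LAPC4, and 0.49 in U87 and 0.14 in SF268. The lines were not tested as pairs. The genes with the strongest single differences were lower in the FDG-high lines, among them UBE2QL1 (-5.21, SE 0.45), the growth factor gene MDK (-4.92, SE 0.57) and the surface protein gene CD24 (-6.84, SE 0.81), and none passed the test across all genes. The FDG-high signal of UBE2QL1 and MDK lay below the array median, so these sizes depend on the pseudocount: UBE2QL1 differed by -5.72 with a pseudocount of 1 and -4.38 with 64, MDK by -5.02 and -4.65.

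Within the glycolysis list, the largest moderated statistics belonged to GPI (0.97, SE 0.57), PFKFB3 (0.77, SE 0.52; 0.38 without U87) and PFKFB4 (0.72, SE 0.50; 0.36 without SKmel28). PFKP differed by 2.22 (SE 1.92), which rested on LAPC4 (level 7.64, where the other 5 lines lay at 13.5 to 15.4), and by -0.00788 without that line. PGK1 differed by 0.32, LDHA by 0.21, ALDOA by 0.20, PKM by 0.20 and ENO1 by 0.14. GAPDH differed by -0.04, a sign that turned to 0.03 under quantile normalization and to 0.08 with array medians subtracted. The hexokinase gene HK2 differed by 1.69 (SE 0.79), and by 0.86 without SKmel28, and HK1 differed by 0.64 (SE 0.62), and by 0.04 without U87. SLC2A1, the gene of the glucose transporter GLUT1, differed by -1.17 (SE 0.58) and SLC2A3 by -0.16 (SE 1.89). Of the pentose phosphate genes, TKT differed by 0.14, PGD by -0.17 and TALDO1 by -0.04, the last turning to 0.08 with array medians subtracted. MYC differed by 0.29 (SE 0.59), MKI67 by 0.21 (SE 0.55), and the MYC target list by a mean of 0.10 over 41 genes (adjusted p = 0.192). With 1 line left out the differences ranged from 0.64 to 1.44 for GPI, 0.17 to 0.44 for PGK1, 0.12 to 0.35 for LDHA, 0.12 to 0.28 for ALDOA, 0.03 to 0.33 for ENO1 and -1.63 to -0.82 for SLC2A1. The sign turned for SLC2A3 (1.63 without LNCAP), PKM (-0.16), TKT (-0.02), PGD (0.04), TALDO1 (0.13), GAPDH (0.05), MYC (-0.16) and MKI67 (-0.27). Such fits leave an origin unmatched: SLC2A3 lay at 7.12 in LNCAP and 7.98 in LAPC4, both prostate lines, and at 11.8 to 12.7 in the others. By origin, SLC2A3 was higher in SKmel28 than in CHL but lower in LNCAP and U87 than in their partners. SLC2A1 was lower in the FDG-high line of each origin. None of these genes passed the test.

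**Figure D1:**
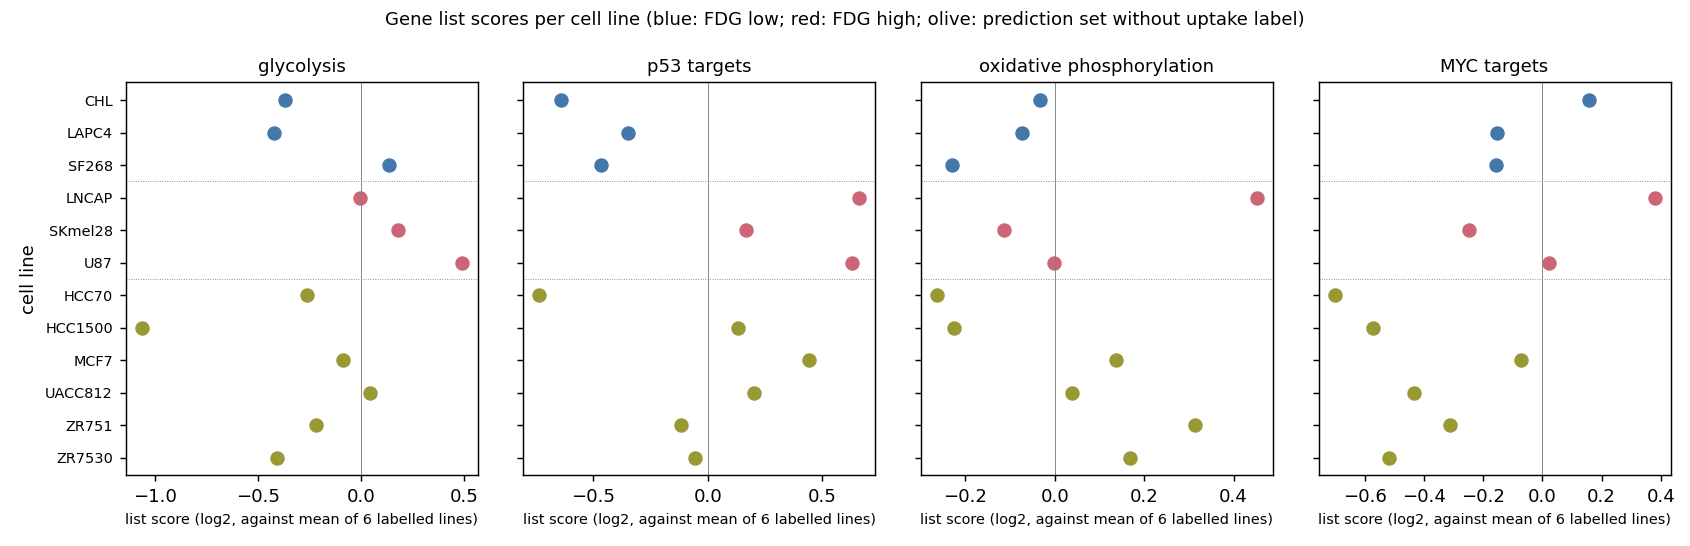
Gene list scores of 12 cell lines, as the mean log2 value of a list's genes against the mean of the 6 labelled lines; blue points are FDG-low, red points FDG-high and olive points the prediction set, each point 1 line. For p53 targets the 3 FDG-high lines sit between 0.16 and 0.66 and the 3 FDG-low lines between -0.64 and -0.35. The glycolysis scores of the groups overlap, though each FDG-high line sits above the FDG-low line of its origin.

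Respiratory chain genes rose by a mean of 0.23, with 38 of 52 members higher (adjusted p = 0.0024, but adjusted p = 0.872 with an estimated correlation, and lost without LNCAP or SF268), with NDUFA3 at 0.68, NDUFB1 at 0.66 and NDUFA5 at 0.77. Antigen presentation genes rose by a mean of 1.00, with 10 of 14 higher (adjusted p = 0.0355, but adjusted p = 0.872 with an estimated correlation), led by the class II genes HLA-DMB (2.05, SE 0.39), HLA-DMA (2.90, SE 1.05) and HLA-DRB1 (3.59, SE 1.701; 5.66 without LNCAP). The call was lost in 8 of 22 alternatives: with quantile normalization, array medians subtracted, the stricter filter, array 1 only or an estimated correlation, and without LAPC4, SKmel28 or U87. LNCAP had the lowest antigen presentation score of the 6 lines (-1.54) and an HLA-DRB1 level (8.32) below that of every FDG-low line. Epithelial adhesion and keratin genes fell by 1.52 in the mean, with 11 of 15 lower (adjusted p = 0.0355, but adjusted p = 0.872 with an estimated correlation, and lost without LAPC4, SKmel28 or U87), among them CD24, KRT8 (-3.05, SE 1.66; -1.35 without LAPC4) and KRT18 (-4.15, SE 2.49; -1.71 without U87, -6.29 without LNCAP). Other genes with strong single differences were SLC24A3 (-5.44), the cadherin gene CDH11 (-6.74) and the activin subunit gene INHBA (-6.38). Higher values were found for LOC105374809 (2.70), the thymidine phosphorylase gene TYMP (2.41), MFAP3L (1.90), PPARGC1B (2.09) and the tyrosine breakdown gene FAH (2.33). The mean log2 level of the lower group lay below the mean array median for SLC24A3, CDH11, INHBA, LOC105374809, TYMP, PPARGC1B and HLA-DMA, so these sizes depend on the pseudocount too.

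With limma, 0 of 12026 tested genes had an adjusted p under 0.05, the smallest being 0.268 for UBE2QL1, and 325 had an unadjusted p under 0.05 where chance gives 601. The groups did not overlap for 425 higher and 454 lower genes, which is 7.31% of those tested where chance gives 10%. Each group held 1 prostate cancer, 1 melanoma and 1 glioma line, and the fit did not pair lines by origin. Spread between origins stayed in the error, so counts below chance do not show that uptake has no effect. Camera called 5 of 33 lists, 4 up and 1 down. With an estimated correlation 0 were called and 2 had an unadjusted p under 0.05. Adjusted over the list alone, 1 epithelial gene and 1 antigen presentation gene passed, and 0 genes of the p53, glycolysis and respiratory chain lists. The exact permutation test of list scores cannot go below p = 0.1 with 3 lines against 3. With 1 line left out, the adjusted p of glycolysis was 0.0210 without SF268, 0.0562 without LNCAP, 0.0735 without SKmel28, 0.0825 without CHL, 0.124 without U87 and 0.137 without LAPC4. The respiratory chain call was lost without LNCAP (mean 0.06, adjusted p = 0.629) and without SF268 (0.17, 0.0616). The epithelial call was lost without LAPC4 (-0.28, 0.634), SKmel28 (-0.39, 0.539) or U87 (-0.27, 0.561), and the antigen presentation call without LAPC4 (1.04, 0.118), SKmel28 (0.40, 0.539) or U87 (0.56, 0.258). Each of these fits left 1 line without its partner of the same origin, so a lost call can reflect origin as well as uptake. The epithelial score was lower in the FDG-high line of each origin. It was -1.73 in SKmel28 and -0.32 in CHL, 1.64 in LNCAP and 3.23 in LAPC4, and -2.19 in U87 and -0.63 in SF268. Without CHL 8 lists were called in place of 5, and the MYC target list passed without CHL (0.20, adjusted p = 0.0345) and without SKmel28 (0.25, 0.0302). Among the arrays written with 1 decimal, which hold 2 lines per group, the p53 score differed by 0.99, the glycolysis list by 0.48 (adjusted p = 0.105) and the MYC target list by -0.09 (0.978).

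The breast tumour comparison asked the same of primary tumours, and the series title names MYC and basal-like cancers. Proliferation genes rose in the FDG-high tumours: all 39 measured members were higher, by a mean log2 fold of 0.75 (n = 5 tumours against 6, adjusted p = 5.5e-24, but adjusted p = 0.125 with an estimated correlation), among them AURKA (0.70, SE 0.17), NUSAP1 (1.11, SE 0.27) and MCM7 (0.90, SE 0.22). The list of mTORC1 and ATF4 stress targets rose by a mean of 0.42 (adjusted p = 5.4e-05, but adjusted p = 0.125 with an estimated correlation). It was led by the asparagine synthetase gene ASNS (1.58, SE 0.23) and the amino acid transporter gene SLC7A5 (2.00, SE 0.32). MYC targets rose by a mean of 0.22, with 29 of 36 higher (adjusted p = 5.4e-05, but adjusted p = 0.125 with an estimated correlation), while MYC itself differed by 0.23 (SE 0.53). Luminal breast genes fell by 1.07 in the mean, with 24 of 25 lower (adjusted p = 4.3e-06, but adjusted p = 0.482 with an estimated correlation and exact permutation adjusted p = 0.413). Markers of adipocytes, fibroblasts, endothelial cells and macrophages were lower in the FDG-high tumours too, by -0.58, -0.55, -0.36 and -0.22.

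**Figure D2:**
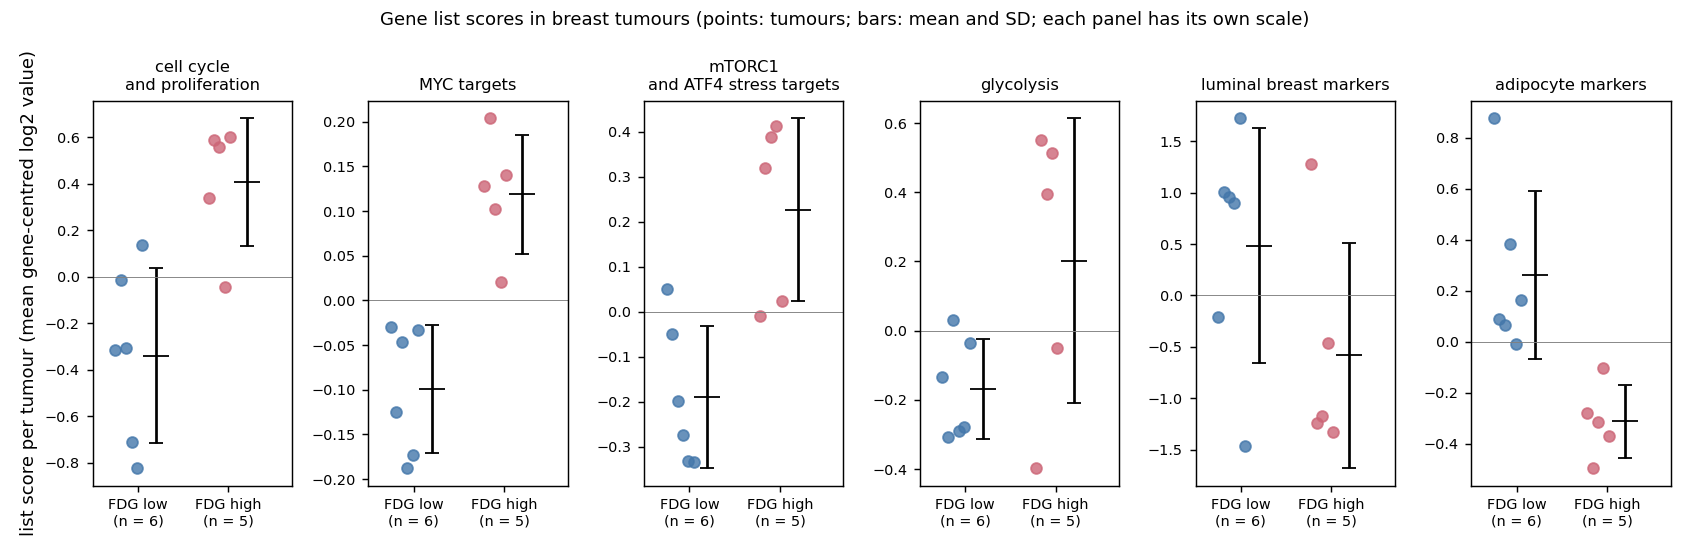
Scores of 6 gene lists per breast tumour, as the mean gene-centred log2 value of the list's measured genes; points are tumours (blue, FDG-low, n = 6; red, FDG-high, n = 5) and bars give the mean and SD of each group. Group means differed by 0.75 for the cell cycle list, 0.22 for MYC targets, 0.42 for the mTORC1 and ATF4 stress list, 0.37 for glycolysis, -1.07 for luminal markers and -0.58 for adipocyte markers.

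MYC target members with the largest statistics were the chaperonin genes HSPD1 (0.78, SE 0.16) and HSPE1 (0.86, SE 0.19) and the cell cycle kinase gene CDK4 (0.70, SE 0.18). The glycolysis list rose by a mean of 0.37, with 14 of 16 members higher (adjusted p = 0.00371, but adjusted p = 0.387 with an estimated correlation and exact permutation adjusted p = 0.239). The difference was 0.212 (SE 0.176) with the luminal score as covariate, 0.590 (SE 0.201) with the stromal score and 0.433 (SE 0.182) with the 3' minus 5' control value, a sign of RNA quality. Its largest statistics belonged to PFKP (1.12, SE 0.38), ALDOC (0.39, SE 0.19) and GPI (0.46, SE 0.23). PKM differed by 0.78 (SE 0.54), ENO1 by 0.36, PGK1 by 0.31, GAPDH by 0.30, LDHA by 0.23 and ALDOA by -0.12. Among the genes of uptake and trapping, SLC2A1 differed by 0.26 (SE 0.20), SLC2A3 by -0.08 (SE 0.27), HK1 by -0.10 (SE 0.28) and HK2 by 0.60 (SE 0.34), with a list mean of -0.03 (adjusted p = 0.959). Of the pentose phosphate genes, PGD differed by 0.41, TKT by 0.60 and TALDO1 by 0.47. With 1 tumour left out the differences ranged from 0.34 to 1.12 for PKM, 0.21 to 0.56 for ENO1, 0.17 to 0.43 for PGK1, 0.17 to 0.46 for GAPDH, 0.12 to 0.32 for LDHA, 0.23 to 0.52 for ALDOC, 0.19 to 0.43 for SLC2A1, 0.39 to 0.76 for HK2 and 0.30 to 0.68 for TALDO1. The sign turned for SLC2A3 (0.07), HK1 (0.18), ALDOA (0.07) and MYC (-0.11). No gene of this paragraph passed the test across all genes.

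Nucleotide synthesis genes rose by a mean of 0.34, with all 20 members higher (adjusted p = 5.4e-05, but adjusted p = 0.177 with an estimated correlation), among them APRT (0.77), CAD (0.59) and DTYMK (0.33). Serine and one-carbon genes rose by 0.38 in the mean (adjusted p = 0.0111, but adjusted p = 0.125 with an estimated correlation), with MTHFD2 at 1.25, SHMT2 at 0.91 and PHGDH at 1.51. The glutamine list rose by 0.45 (adjusted p = 0.00415, but adjusted p = 0.125 with an estimated correlation), which rested on ASNS, SLC7A5 and the proline synthesis gene PYCR1 (0.57), with 7 of 11 members higher. Aminoacyl-tRNA synthetases rose by 0.24 (adjusted p = 0.0111, but adjusted p = 0.199 with an estimated correlation) with 12 of 22 higher, led by YARS1 (0.71), AARS1 (0.64) and CARS1 (0.61). Proteasome genes, included as a control list, rose by 0.19 with 23 of 27 higher (adjusted p = 0.00617, but adjusted p = 0.387 with an estimated correlation), with PSMB2 at 0.69, PSMD14 at 0.57 and PSMC2 at 0.29. This control list had a smaller adjusted p than the serine and aminoacyl-tRNA lists, so a call alone does not single out a pathway. Interferon response genes rose by 0.54 with 29 of 32 higher (adjusted p = 0.00382, but adjusted p = 0.800 with an estimated correlation), with CXCL10 at 1.46, TAP1 at 0.90 and IFI44L at 1.20 (0.74 without FDG-high replicate 1). The difference was 0.125 (SE 0.609) with the stromal score as covariate, 0.818 (SE 0.551) with the luminal score and 0.439 (SE 0.530) with the 3' minus 5' value. Glycolysis kept 57.2% of its difference with the luminal score as covariate. Apart from fibroblast and luminal genes, the other called lists kept 61.0% (nucleotide synthesis, luminal score) to 171% (macrophages, luminal score) with these 3 covariates. The stromal score is the mean of the fibroblast, adipocyte and endothelial scores. With it, the adipocyte (80.9% kept) and endothelial (68.8%) differences are adjusted in part for themselves. The stromal marker scores were lower in the same tumours, by -0.50 for their mean (exact permutation p = 0.0519).

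The luminal list had its largest statistics in SCUBE2 (-2.65, SE 1.03), CA12 (-2.11, SE 0.95) and MLPH (-1.52, SE 0.69). ESR1, the oestrogen receptor gene, differed by -1.91 (SE 1.25), GATA3 by -0.79 (SE 0.83), the basal keratin gene KRT5 by 1.07 (SE 0.77), EGFR by 0.04 and ERBB2 by 0.08. With 1 tumour left out EGFR ranged from 0.00118 to 0.09 on the same probe set and was 0.72 where another probe set was chosen, and ERBB2 became -0.68 (without FDG-high replicate 4), KRT5 0.47 (without FDG-high replicate 3), ESR1 -3.01 and GATA3 -0.49. The basal-like list differed by a mean of 0.33 with 13 of 18 higher (adjusted p = 0.244). Adipocyte markers fell (adjusted p = 0.00203, but adjusted p = 0.125 with an estimated correlation), with FABP4 at -2.00, LPL at -0.99 and CEBPA at -0.52. Fibroblast and matrix markers fell (adjusted p = 0.00102, but adjusted p = 0.800 with an estimated correlation, and lost without FDG-high replicate 1), with 24 of 26 lower, among them DCN (-1.34), TIMP3 (-1.06; -0.70 without FDG-high replicate 5) and CTSK (-0.89). The difference of fibroblast and matrix markers was -0.194 (SE 0.481; 35.3% kept) with the 3' minus 5' value as covariate and -0.625 (SE 0.702) with the luminal score. With the stromal score it turned to 0.714 (SE 0.264), but this list is part of that score, so the value cannot be read. Endothelial markers fell (adjusted p = 0.00218, but adjusted p = 0.125 with an estimated correlation), with CLDN5 at -0.52, PECAM1 at -0.62 and EGFL7 at -0.35. Macrophage markers fell (adjusted p = 0.0474, but adjusted p = 0.800 with an estimated correlation). Their call was also lost with the stricter filter and without any 1 of 6 tumours. CX3CR1 differed by -1.49, CD14 by -0.37 (-0.24 without FDG-low replicate 6) and VSIG4 by -0.24 (-0.37 without FDG-low replicate 2). The proliferation marker MKI67 differed by 0.43 (SE 0.18).

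Outside the lists, the metal-binding metallothionein genes MT1X (1.43, SE 0.25) and MT1H (1.25, SE 0.23), whose sequences are alike enough for a probe set to read paralogs, and the mitochondrial nucleoside kinase gene DGUOK (0.65, SE 0.12) were higher in every FDG-high tumour than in any FDG-low tumour. SELENBP1 (-1.62, SE 0.28), TOR1AIP1 (-1.02), CMAHP (-1.90), SYBU (-1.42), the RNA helicase gene DDX17 (-0.51) and PRKAR1A (-0.57), a regulatory subunit of protein kinase A, were lower in every FDG-high tumour. The FDG-high means of CMAHP, SYBU, FABP4, CLDN5 and CX3CR1 lay below the array median, so these sizes depend on the pseudocount. The groups did not overlap for 63 higher and 21 lower genes, 1.16% of those tested where chance gives 0.433%.

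With limma, 0 of 7235 tested genes had an adjusted p under 0.05 (smallest 0.132, shared by 16 genes), and 767 had an unadjusted p under 0.05 where chance gives 362. Adjusted over the list alone, 31 proliferation genes, 5 mTORC1 and ATF4 stress genes, 3 MYC targets, 3 glutamine genes, 3 serine and one-carbon genes, 2 aminoacyl-tRNA synthetases, 1 proteasome gene, 1 nucleotide synthesis gene and 1 macrophage marker passed, and 0 glycolysis or luminal genes. Among the passing genes, ASNS and SLC7A5 counted for both stress and glutamine, and PHGDH and MTHFD2 for both stress and serine. Camera called 15 of 34 lists, 10 up and 5 down. Some of these share genes, so their calls are not independent. In another called list were 6 of 20 stress, 3 of 11 glutamine and 5 of 13 serine and one-carbon members. With an estimated correlation 0 were called and 8 had an unadjusted p under 0.05. At its preset correlation camera also called lists in nearly all other splits of these tumours, up to 19. A small adjusted p at that setting therefore does not by itself show a difference that goes with uptake. The two-sided exact permutation test of list scores over 462 splits gave adjusted p values of 0.0245 for MYC targets, glutamine and aminoacyl-tRNA synthesis, 0.0368 for adipocyte and 0.0442 for serine and one-carbon genes. By the same exact permutation the adjusted p was 0.0526 for proliferation and for mTORC1 and ATF4 stress, 0.0654 for nucleotide synthesis and endothelial, 0.239 for glycolysis and proteasome, 0.413 for luminal, 0.704 for interferon, 0.706 for macrophage and 0.719 for fibroblast genes. Without FDG-low replicate 2 the count of genes was 4 in place of 0, without FDG-high replicate 4 it was 3 and without FDG-high replicate 1 it was 1. Without FDG-high replicate 1 the call was lost for interferon (mean 0.38, adjusted p = 0.106), aminoacyl-tRNA (0.22, 0.101), fibroblast (-0.33, 0.0962), glutamine (0.39, 0.0632), serine and one-carbon (0.35, 0.0632) and macrophage lists (-0.09, 0.646), and 10 lists were called in place of 15. The macrophage call was also lost without FDG-high replicate 2 (-0.21, 0.0644) or 4 (-0.24, 0.0574) and without FDG-low replicate 2 (-0.19, 0.108), 3 (-0.16, 0.154) or 6 (-0.21, 0.117). The basal-like list passed without FDG-high replicate 1 (0.69, adjusted p = 0.00736) and without FDG-low replicate 6 (0.66, 0.00859).

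Across the 11 tumours the glycolysis score was set against 7 other list scores, and none of the relations passed the correction. The luminal score gave Pearson r = -0.68 (permutation p = 0.0278, adjusted p = 0.195) and Spearman rho = -0.65 (p = 0.0375, adjusted p = 0.157), r = -0.69 without the 2 tumours farthest from the median, and r = -0.57 with the group means removed. The basal-like score gave r = 0.52 (permutation p = 0.0987, adjusted p = 0.230) and rho = 0.63 (p = 0.0447, adjusted p = 0.157), r = 0.74 without those 2 tumours and r = 0.51 with the group means removed. For MYC targets r was 0.56 (permutation p = 0.0777, adjusted p = 0.230), rho was 0.45 (p = 0.162, adjusted p = 0.379), r was 0.42 without the 2 farthest tumours and 0.16 with the group means removed. The cell cycle score gave r = 0.48, the hypoxia score r = 0.38, the macrophage score r = 0.30 and the fibroblast score r = 0.26, with adjusted permutation p values of 0.235, 0.346, 0.427 and 0.427. In that order r was 0.46, -0.31, 0.71 and 0.19 without the 2 farthest tumours, and 0.07, 0.44, 0.64 and 0.55 with the group means removed.

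The astrocytoma comparison set 1 FDG-high against 1 FDG-low sample, because the 2 arrays of a label lay far closer to each other than any 2 breast tumours did. Arrays of different labels (robust SD 0.293 to 0.302) also lay closer than any 2 breast tumours (lowest 0.357). Whether the labels came from different tumours is therefore not known. Hypoxia genes stood higher in the FDG-high astrocytoma by a mean log2 fold of 1.19 over 26 genes, among them the angiogenic factor gene VEGFA (2.80), NDRG1 (2.85) and the matrix enzyme gene LOX (3.77). Glycolysis genes stood 0.54 higher, with LDHA at 2.05, ENO2 at 1.74 and PGK1 at 1.299. The genes with the largest folds that stood higher included LTF at 3.88, CHI3L2 at 4.46, PLA2G2A at 4.25, PI3 at 4.08 and SLPI at 3.997. The FDG-low signal of LOX, PI3 and SLPI lay below the array median and that of CHI3L2 and PLA2G2A little above it. The sizes and order of these 5 depend on the pseudocount: LOX differed by 5.61 with a pseudocount of 1 and by 2.25 with 64. The immediate-early genes FOSB (-2.75), FOS (-1.89) and EGR3 (-1.61) and the glial proteoglycan genes NCAN (-2.54) and CSPG5 (-2.02) stood lower, as did the chemokine gene CCL4 (-2.10). The FDG-high level of FOSB (4.45) lay little above the array median, so its size depends on the pseudocount too. The 2 arrays of a label could not be shown to be independent replicates, so no p is given for these samples.

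Further glycolysis and uptake genes in the astrocytomas included SLC2A3 (1.99), HK2 (1.31), ENO1 (1.00), PKM (0.94), PFKP (0.85), GAPDH (0.54), ALDOA (0.52), GPI (0.45) and HK1 (0.28). SLC2A1 differed by -0.02, which became 0.02 under quantile normalization. MYC differed by 0.38, PGD by 0.06, TKT by 0.03 and TALDO1 by 0.07, and MKI67 was below the filter. With 1 array left out PGD turned to -0.00628 and TKT to -0.00455. The MYC target list differed by -0.02 in the mean and by 0.00142 in the median, at percentile 78.1 of random lists of like expression.

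**Figure D3:**
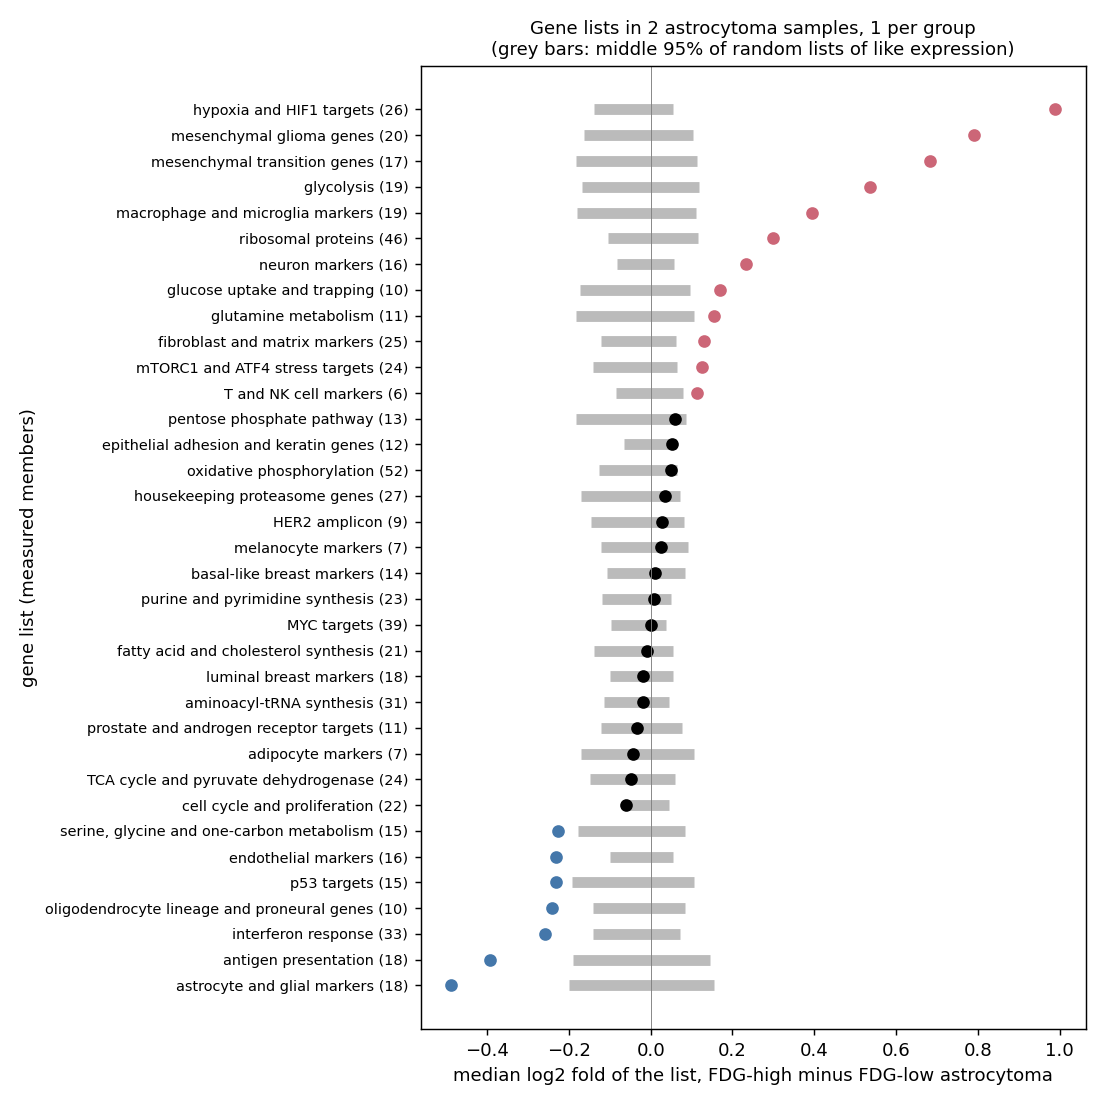
Median log2 fold of 35 gene lists between the FDG-high and the FDG-low astrocytoma; points are lists (red, above and blue, below the middle 95% of random lists of like expression, shown as grey bars; black, inside them). The hypoxia list lies highest at 0.99 and the astrocyte and glial list lowest at -0.49.

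Of 35 lists, 12 stood above and 7 below the middle 95% of random lists of like expression, which describes these 2 samples and is no test of uptake. Above them were mesenchymal glioma genes (mean 0.89; MET at 2.25, CHI3L1 at 1.71), mesenchymal transition genes (0.77; NNMT at 2.74, CAV1 at 2.08, CD44 at 1.62) and uptake and trapping genes (0.40; HK3 at 0.28). Macrophage and microglia markers (0.36; MRC1 at 1.11, VSIG4 at 0.94, CD14 at 0.74) and neuron markers (0.39; ENO2 at 1.74, NEFL at 1.298, STMN2 at 1.26) stood above too. T cell markers (0.14 over 6 tested of 24; IL7R at 0.42, CD4 at 0.25, CCL5 at 0.24) and fibroblast and matrix markers (0.28; TAGLN at 1.77, FN1 at 1.23, TIMP1 at 1.16) also stood above. So did ribosomal proteins (0.33; RPL27 at 0.64, RPS3 at 0.62, RPS29 at 0.62), glutamine genes (0.14; SLC38A1 at 1.31, GLUL at 0.54, ALDH18A1 at 0.29) and mTORC1 and ATF4 stress genes (0.04; HSPA5 at 1.03, VLDLR at 0.97, DNAJB9 at 0.65, against SLC7A5 at -1.17 and ATF3 at -1.17). Of these genes MRC1, NEFL and STMN2 lay below the array median in the FDG-low sample. MET (4.43), IL7R (4.40), CCL5 (4.44) and HK3 (4.49) lay little above it, so the sizes of all these genes depend on the pseudocount. Below them were astrocyte and glial genes (-0.48; BCAN at -1.13), oligodendrocyte lineage genes (-0.43; OLIG2 at -1.54, OLIG1 at -1.49, SOX8 at -1.39) and endothelial markers (-0.33; CLDN5 at -1.14, ROBO4 at -0.93, VWF at -0.92). Antigen presentation genes (-0.41; TAP2 at -0.83, HLA-E at -0.82, HLA-DQA1 at -0.68), interferon genes (-0.17; TAP1 at -0.92, IRF1 at -0.90, OAS3 at -0.66), p53 targets (-0.28; GDF15 at -1.56, CDKN1A at -0.62, ZMAT3 at -0.50) and serine and one-carbon genes (-0.19; ALDH1L1 at -0.68, TYMS at -0.57, SLC1A4 at -0.47) stood below as well. Some lists shared leading genes, so the 12 that stood above are not independent. LOX was in the hypoxia and mesenchymal glioma lists, PGK1 in hypoxia and glycolysis, and SLC2A3 in hypoxia and uptake. ENO2 was in the glycolysis and neuron lists and CD44 in both mesenchymal lists. In all, 132 of 12815 genes stood at least 2-fold higher and 55 at least 2-fold lower in every pairing of arrays. This count of 187 became 369 with a pseudocount of 1 and 80 with a pseudocount of 64.

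The genes that differed most between the cell lines were then read in the tumours. A score from the 100 highest and 100 lowest of them differed between the breast groups by -0.09 (exact permutation p = 0.561, two-sided, n = 5 against 6) and between the astrocytomas by 0.21, untested. The astrocytoma difference turned to -0.20 when U87 was left out of the choice of genes and became 0.69 without SKmel28, and the breast difference turned to 0.32 without CHL (exact permutation p = 0.0584). Across genes, the log2 folds of cell lines and breast tumours correlated with r = 0.06 over 6490 genes, those of cell lines and astrocytomas with r = 0.05 over 10765 and those of breast tumours and astrocytomas with r = 0.04 over 6841; genes are not independent replicates. None of 31 lists differed in effect between cell lines and breast tumours after correction by a permutation test over 9240 relabellings; p53 targets came nearest (0.97 against -0.01, permutation p = 0.0451, adjusted p = 0.912) and were the only list with an unadjusted p under 0.05. The difference between 3' and 5' control values, a sign of RNA quality, was -0.01 between the cell line groups (exact permutation p = 0.8), 0.15 between the breast groups (exact permutation p = 0.418) and -0.10 between the astrocytomas.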

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

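The tests of export style and TP53 status in the cell lines and of neutrophil and immediate-early genes in the astrocytomas were chosen only after the results were seen.

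The cell cycle list stood higher in FDG-high breast tumours by 0.75, and markers of stromal cells and luminal genes stood lower in the same tumours. With the 3' minus 5' control value as covariate the difference was 0.662 (SE 0.198), which kept 88.6% of its value, and argues against RNA quality as the whole cause. With the stromal score as covariate it was 0.482 (SE 0.221; 64.5% kept), and with the luminal score 0.553 (SE 0.193; 74.1% kept), so a lower share of stromal cells or of luminal features may account for part of it and cannot be told apart from uptake. The stromal score differed between the groups by -0.50 (exact permutation p = 0.0519) and the luminal score by -1.07 (exact permutation p = 0.158), and 11 tumours are too few to separate them. The stromal score correlated with the cell cycle score at r = -0.76. A difference in uptake itself remains open and was not tested apart from these.

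Targets of p53 stood higher in the 3 FDG-high cell lines by 0.971. Among arrays written with 1 decimal the difference was 0.994 (SE 0.230), which argues against the mixing of export styles as its cause. From background knowledge LNCAP and U87 carry intact TP53, and their scores lay above those of the other 4 lines. SKmel28 lay 0.514 above the highest FDG-low line, where the SD between the FDG-low lines was 0.146, but this is a lone line, so TP53 status may still account for much of the difference and cannot be told apart from uptake.

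In the FDG-high astrocytoma hypoxia genes and LTF, CHI3L2, PLA2G2A, PI3 and SLPI stood higher and immediate-early genes lower. The median of a list of 14 neutrophil genes, 0 of them in another list, was 0.227 (SD between pairings 0.0148), with 12 higher, which neutrophils could give. The clearest were S100A8 (3.27; level 7.95 against 4.68), S100A9 (2.01; 6.60 against 4.60) and TREM1 (2.497; 6.94 against 4.44), which also belong to other myeloid cells. Their FDG-low levels lay little above the array median, so these sizes depend on the pseudocount. FCGR3B differed by 0.30, CSF3R by -0.04 and CXCR2 by -0.01, so neutrophils cannot be told apart from another source. All 18 immediate-early genes were lower, with a median of -1.26 (SD 0.0234), as a difference in tissue handling could give. With 1 sample per label this cannot be told apart from another difference between the samples. Some of these genes were part of the pattern itself, and no biological explanation was tested.

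Other splits of the same samples were counted. For the cell lines 3 against 3 make 10 splits, too few for a share under 0.05. All 10 gave at least the real count of 0 genes (highest of the others 6), 7 gave at least 325 genes with an unadjusted p under 0.05 (highest 1344) and 8 gave at least 5 lists (highest 15). The other splits balanced by origin, as the real one is, gave 230, 307 and 225 genes with an unadjusted p under 0.05. They gave 3, 5 and 5 lists. All splits with more than 325 such genes put both lines of an origin on the same side, so their counts also carry origin. The balanced splits are too few for a test. The highest count of genes by unadjusted p came from CHL, LAPC4 and LNCAP against the rest. The highest list count came from CHL, SF268 and SKmel28 against the rest, so the lines hold structure other than uptake. For the breast tumours 100 of the splits were drawn. All 100 gave at least the real count of 0 genes (highest of the others 33), which no split could fail to do, so this count tests nothing. Of the same splits 8 gave at least 767 genes with an unadjusted p under 0.05 (highest 1059) and 7 gave at least 15 lists (highest 19). Nearly all the other splits called some lists, from 0 to 19, so camera at its preset correlation often calls lists without regard to uptake. Chance was not excluded for the last 2 breast counts.

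Samples that lay far from the rest of their group were sought in 270 sets of values, and 27 were found where chance gives 13.5. Among FDG-high breast tumours, replicate 4 lay apart with both a HER2 amplicon score of 2.41 and an ERBB2 value of 13.4. Replicate 1 had a low mesenchymal glioma score (-0.97), low PHGDH (7.67) and high ESR1 (12.6). HK1 was low in replicate 3 (9.48), and replicate 5 had low PGD (8.38) and a high 3' minus 5' control value (0.74). Among FDG-low breast tumours, replicate 6 had a high basal-like score (1.52). It also had a low uptake and trapping score (-0.50), GATA3 (8.45), CA12 (6.51) and MLPH (9.24). High values in replicate 2 were an interferon score of 1.47 and SLC2A1 at 9.28, and in replicate 1 MTHFD2 at 10.5 and CLDN5 at 8.31. Several values come from the same tumours, so the finds are not independent.

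In the prediction set HCC70 lay apart with a basal-like score of 0.96, a luminal score of 0.33, a mesenchymal transition score of -1.06, a mesenchymal glioma score of 1.04, KRT5 at 16.9 and EGFR at 14.3. HCC1500 lay low in PFKP (7.19) and in the cell line signature score (-0.46). UACC812 lay high in the adipocyte marker score (0.75) and ZR7530 low in PGK1 (16.6).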

How the results depend on the processing

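The alternatives with a pseudocount of 0 or above 64 and those using export style were chosen only after the results were seen. No result that had passed a test changed its direction in any of these processing alternatives. The cause was not tested for any change below, except that the estimated correlation widens the test by construction. With array medians subtracted, the median fold of all cell line genes moved from -0.03 to 0.09. For the astrocytomas the prior of eBayes, an estimated correlation, a replicate block and a joint fit with the cell lines were not run, since each label counted as 1 sample on a scale of its own. Low signal limits dim genes, as the pseudocounts show.

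In the cell lines the count of genes was 0 in every alternative. The count of lists, 5, became 3 with quantile normalization, 3 with array 1 of each line, 0 with an estimated correlation, and 8 with all 12 arrays and line as random block; with array number as replicate block it was 8 too, and with export style as block 8 (consensus correlations 0.885, 0.903 and 0.912). Leaving out 1 line gave 4 to 8. Every such fit left another line without its partner of the same origin, so changes in it can reflect origin as well as uptake. The glycolysis mean, 0.44, was no longer past the threshold with quantile normalization (0.45, adjusted p = 0.0550), no filter (0.38, 0.107), array 1 only (0.40, 0.0601), an estimated correlation (0.44, 0.617) and 1-decimal arrays only (0.48, 0.105), and ranged from 0.31 to 0.61 with 1 line left out. The MYC target mean became -0.091 with 1-decimal arrays only and ranged from -0.064 (without LNCAP) to 0.25 with 1 line left out. The p53 call was lost in 1 of 22 alternatives, the respiratory chain call in 4, the epithelial call in 6 and the antigen presentation call in 8.

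In the breast tumours the count of genes stayed 0 except in 3 of the 11 leave-out fits (0 to 4). The count of lists fell from 15 to 0 with an estimated correlation and was 10 to 17 with 1 tumour left out. With the stricter filter it was 12 of 28 tested lists, and the macrophage call was lost there. Among these alternatives glycolysis (0.37, adjusted p = 0.387) and MYC targets (0.22, 0.125) lost their calls only with an estimated correlation, but the exact permutation test gave glycolysis an adjusted p of 0.239. With 1 tumour left out they ranged from 0.28 to 0.52 and from 0.20 to 0.24. The signature difference became 0.037 with 250 genes per direction and ranged from -0.19 to 0.32 with 1 sample left out.

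In the astrocytomas the count of genes, 187, became 369, 80 and 396 with pseudocounts of 1, 64 and 0, 119 with the mean of all probe sets, and 199 to 207 with 1 array left out. The count of lists, 19, was 17 with no filter and with the stricter filter, 18 with the mean of all probe sets, 20 with quantile normalization and with pseudocounts of 1 and 0, and 19 to 21 with 1 array left out. The glycolysis mean became 0.60, 0.45 and 0.60 with those pseudocounts, 0.51 with no filter, 0.57 with the stricter filter and 0.43 with the mean of all probe sets (0.53 to 0.55 with 1 array left out). The MYC target mean became 0.00926 with quantile normalization, -0.022 with medians subtracted, and -0.033, -0.00621 and -0.036 with those pseudocounts (-0.020 to -0.012 with 1 array left out). The signature difference became 0.10 and 0.56 with 50 and 250 genes per direction, 0.25 with quantile normalization, 0.25 with a pseudocount of 1, 0.17 with no filter and 0.55 with the mean of all probe sets, and ranged from -0.20 (without U87) to 0.69 (without SKmel28).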

Other observations

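The genes and lists named in this part were picked after their values were seen. The 6 breast cancer lines of the prediction set were set against the 6 labelled lines. Their glycolysis scores ran from -1.07 in HCC1500 to 0.04 in UACC812, and their MYC target scores from -0.70 in HCC70 to -0.07 in MCF7, with labelled lines between -0.25 and 0.38. MCF7 had an interferon score of 3.42, where the labelled lines ran from -1.45 to 1.11. The HER2 amplicon score was 3.85 in UACC812 and 2.71 in ZR7530, with ERBB2 values of 17.1 in each. SLC2A1 had its highest values in ZR751 (13.9) and HCC1500 (13.8).

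Among lists not called in the cell lines, melanocyte markers differed by a mean of 1.48 (adjusted p = 0.107), a difference carried by SKmel28, whose score was 4.55. Cell cycle genes differed by 0.20 (adjusted p = 0.107) and hypoxia genes by 0.09 (0.571). In the breast tumours respiratory chain genes differed by -0.08 (adjusted p = 0.096), hypoxia genes by 0.02 (0.277), antigen presentation genes by -0.10 (0.545), T cell markers by 0.14 (0.570) and ribosomal proteins by -0.01 (0.668). In the astrocytomas cell cycle genes stood at -0.16 in the mean, at percentile 3.33 of random lists. For a few lists the signs of mean, median and test differ, all of them uncalled: pentose phosphate, endothelial, fibroblast and oligodendrocyte lists in the cell lines, p53, TCA cycle, B cell, mesenchymal glioma and uptake lists in the breast tumours, and MYC target, nucleotide synthesis, luminal and prostate lists in the astrocytomas, where no test was made.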
